A study of Mus musculus with 20 samples.

How the data were processed

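RNA was measured in 20 libraries of mouse motor cortex: input RNA and polysome-immunoprecipitated (IP) RNA, each from the hemicortex ipsilateral and contralateral to a viral injection, with 5 replicates of 3 pooled mice in each of the 4 groups. Per the labels, tissue was kept in cycloheximide, which holds ribosomes on mRNA, and 2 of the 5 replicates came from males and 3 from females. The authors deposited 1 table of TPM, with 24091 genes and a column for each library. Per the submitters' processing notes, the build was mm10, and Subread and featureCounts are named. Their versions, the annotation, the aligner's settings, the step from counts to TPM and the use of strand are not given in the sources used here. TPM divide each gene's reads by its length and scale each library to a fixed sum. The columns each summed to between 999837 and 999922, so a gene with many reads lowers all others, and the read depth behind each value is unknown. Genes at 0 made up 25.27 to 41.43% of the table per library. A test on counts had been planned in case of counts, and limma on log2(TPM + 1) in case of TPM alone. The latter was used.

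Columns were matched to samples by the replicate number, side and fraction in their names, and 0 columns were without a sample. Gene IDs were NCBI gene IDs, of which 24045 matched a RefSeq gene table of GRCm38.p6, the assembly called mm10, from which coordinates and gene types were taken. A further 26 symbols that had turned into dates were restored through it. Ribosomal protein, globin and small-RNA genes share reads with copies or host genes and are uncertain.

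Each of 4 pair comparisons (contra IP and contra input, ipsi IP and ipsi input, contra IP and ipsi IP, contra input and ipsi input) was fitted to its 10 libraries, and the difference of IP enrichment between sides to all 20. Genes with a TPM of at least 1 in at least 5 libraries of the fit were kept, log2(TPM + 1) was taken, and limma 3.58.1 (lmFit, eBayes with a trend; R 4.3.3) was run with the replicate number as a block and Benjamini-Hochberg adjustment within each comparison. Genes at an adjusted p under 0.05 were called. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and ± beside a fold change is its standard error from limma. The number behind each TPM mean ± SD is 5. The labels give the pairing, since all 4 libraries of a replicate come from the same mice. Correlations of same-numbered libraries' deviations from their group means ran from -0.025 to 0.258. Between contra IP and ipsi IP, those of replicates 1 and 7 (0.113 and 0.045) were below the highest with another number (0.166 and 0.072). Those of replicates 2, 4 and 5 were above it. The values thus show the pairing weakly, and the block rests on the labels. As a check of sample identity, the list of sex-linked genes was read in each library. Ddx3y, on the Y chromosome, was at 17.7 to 40.4 TPM in the 8 libraries of replicates 1 and 2 and at most 0.0786 TPM in the other 12, so no replicate mixed both levels. The list was tested in the difference of enrichment alone (4 genes, 0 called by limma, camera adjusted p = 0.80, and adjusted p = 0.86 with an estimated correlation). Replicate columns were compared within each group and 0 were identical.

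Gene lists were fixed before the data were examined: layer 5b corticospinal neurons, intratelencephalic neurons of layers 2 to 4, intratelencephalic and near-projecting neurons of layer 5, neurons of layer 6, excitatory neurons in general, interneurons, astrocytes, oligodendrocytes and their precursors, microglia, vascular and meningeal cells, blood, choroid plexus, striatum and subcortex, axon guidance, axon growth and regeneration, neurofilaments and axonal transport, voltage-gated channels, immediate early genes, interferon response, mitochondrially encoded genes, nuclear noncoding RNA, ribosomal proteins, nuclear-encoded oxidative phosphorylation, sex-linked genes, and Rpl10a as its own list. Lists of at least 4 tested genes were tested on log2(TPM + 1) with limma's camera, which compares a list with all other genes, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over the lists of a comparison. None of the 48 list calls held with an estimated correlation. That version of camera has little power with so few libraries in a fit. In contra IP against input, 18 of 20 layer 5b genes were higher, yet its adjusted p was 0.12. A list that it does not call is thus not shown to be unchanged. The preset correlation is an assumption in turn. Its p is too small where genes of a list vary together by more than that, so its size does not measure agreement between the 5 pairs. Camera's direction is relative to the other genes, so it can differ in sign from a list's own median. Members called are given over all genes and, where it differs, adjusted over the list alone.

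Genes are named by a rule fixed before the data were examined: per comparison, the 10 called genes with the largest fold change in each direction that moved the same way in all 5 pairs and have a mean TPM of at least 5, leaving out unnamed gene models and pseudogenes; where fewer than 10 genes were called, all of them and the 10 with the smallest p; called list members, up to 4 per list and direction; and Bcl11b, Fezf2, Crym, Slc17a7, Gad1, Aqp4, Mbp, Cx3cr1, Cldn5 and Rpl10a in the IP comparisons. Mir6236, Npnt, the Snhg genes that are not among the largest changes, and Gm12505, Lrguk and Rsph3b were named outside the rule, after their values were seen. Results of some genes that the rule picks are not reported here, though counts include them.

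Alternatives set before the data were examined were a pseudocount of 0.1, no filter and a stricter filter on low values, no replicate block, each replicate left out in turn, replicates 1, 2 and 4 or 5 and 7 alone, a fit on all 20 libraries, a block by side, and a test of IP-enriched genes alone. Median-ratio scaling (over 10433 genes at a TPM of at least 1 in all libraries, with factors from 0.8327 to 1.195), the same with no block, and sample quality weights were added after the data were seen. The model was tested on simulated data in which 200 genes were changed. At log2 changes of 0.5, 1 and 2 it recovered 41.8, 95.5 and 100% of them in the contra IP to input comparison (12917 genes), 16.4, 64.2 and 95.5% in the ipsi one (12997 genes), 25.4, 74.6 and 98.5% between the IPs (12011 genes), 47.8, 88.1 and 100% between the inputs (13380 genes) and 16.4, 59.7 and 98.5% in the difference of enrichment (13689 genes). False calls made up 4.2, 7.1, 3.6, 3.7 and 4.9% of all calls. The changed genes were drawn from those above a bound on mean level, and errors were drawn independently for each gene. These rates thus do not cover low genes, errors shared between genes or a change of most genes. For the check on length, the longest GENCODE transcript of each symbol was used, which 11776 of the 12011 genes tested between the IPs had (98.04%). Library measures and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. An IP from cortex without the virus was not analysed here, so the background of the pulldown is not measured.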

Results

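RNA bound to tagged ribosomes was compared with total input RNA from mouse motor cortex, on both sides of the brain. In translating ribosome affinity purification (TRAP), a tag on the ribosomes of chosen cells lets their polysomes, and the mRNA on them, be pulled down with an antibody. The tag was delivered here by a virus injected into the spinal cord on one side and carried back along axons to corticospinal neurons (CSNs), the neurons of cortical layer 5b whose axons descend to the spinal cord. Each hemicortex, ipsilateral (ipsi) or contralateral (contra) to the injection, gave an input library and an immunoprecipitated (IP) library. The 4 groups (contra IP, contra input, ipsi IP and ipsi input) held 5 replicates each, numbered 1, 2, 4, 5 and 7, or 20 libraries. Each replicate pooled 3 mice, separate from those of the other replicates, and its 4 libraries came from the same mice. Per the labels, 7 replicates had been processed, and 2 libraries were left out by the submitters because of markers of cells outside layer 5b or of non-neuronal cells, so marker levels in the IPs that were kept had already been a criterion for keeping them. All libraries of the remaining replicates are absent here, which is more than those 2, and the reason is not given in the sources used here.

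The values were TPM, read counts divided by gene length and scaled to a fixed sum per library. They do not keep the read depth, so the depth behind each value is unknown. The table held 24091 genes. Genes at a TPM of at least 1 numbered 13366 ± 75.2 in contra input, 13430 ± 45.8 in ipsi input, 11811 ± 86.5 in contra IP and 12211 ± 242 in ipsi IP (SD, n = 5 each). Pearson correlations of log2(TPM + 1) across genes, between replicates of a group, ran from 0.978 to 0.988 in contra IP, from 0.937 to 0.972 in ipsi IP, from 0.986 to 0.991 in contra input and from 0.973 to 0.987 in ipsi input. Genes are not independent replicates. A single gene model, Mir6236, which was singled out after its values were seen, took 24.5% ± 3.66 of the TPM in contra IP, 24.9% ± 7.19 in ipsi IP, 18.9% ± 4.32 in contra input and 16.5% ± 4.91 in ipsi input (SD, n = 5 each). This lowers the TPM of all other genes in the same library. The median gene lay at log2 -0.35 in the contra and -0.30 in the ipsi IP to input comparison. Median-ratio scaling, added after the data were seen, moved genes up by a median of 0.29 (log2) in the contra IP to input comparison, 0.23 in the ipsi one, 0.11 between the IPs and 0.05 between the inputs. The total counts of called genes are given on both scales below. Counts within lists are as deposited unless scaling is named, and some of them moved with it. In contra IP against input, for example, interferon-response genes called lower went from 6 to 4, and axon growth genes from 14 to 11.

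The contra IP was compared with its input to ask which transcripts were on the ribosomes of contralaterally projecting CSNs. Genes of layer 5b corticospinal neurons were higher in the IP. Crym, a thyroid hormone-binding protein used as a marker of subcerebral projection neurons, had 256 ± 8.64 TPM in contra IP and 49.6 ± 2.73 TPM in contra input (SD, n = 5 each), 5.08-fold higher (log2 2.35 ± 0.06 SE). Fezf2, the transcription factor that specifies subcerebral projection neurons, had 232.6 ± 7.64 and 58.2 ± 4.23 TPM and was 3.95-fold higher (log2 1.98 ± 0.06 SE). Markers of interneurons and glia were lower. Gad1, an enzyme of GABA synthesis, went from 97.8 ± 9.27 TPM in input to 16.9 ± 11.4 TPM in IP (log2 -2.70 ± 0.27 SE). Aqp4, the water channel of astrocytes, went from 20.7 ± 3.53 to 2.03 ± 1.08 TPM (log2 -2.90 ± 0.20 SE), and Mbp, a myelin protein of oligodendrocytes, from 252.1 ± 17.7 to 35.8 ± 6.44 TPM (log2 -2.80 ± 0.08 SE, with SD of TPM and n = 5 each). Each of these 5 genes moved the same way in 5 of 5 pairs and was called by limma (adjusted p = 2.7e-09 for Crym, 5e-09 for Fezf2, 1.3e-05 for Gad1, 9.8e-07 for Aqp4 and 4.4e-09 for Mbp).

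**Figure D1:**
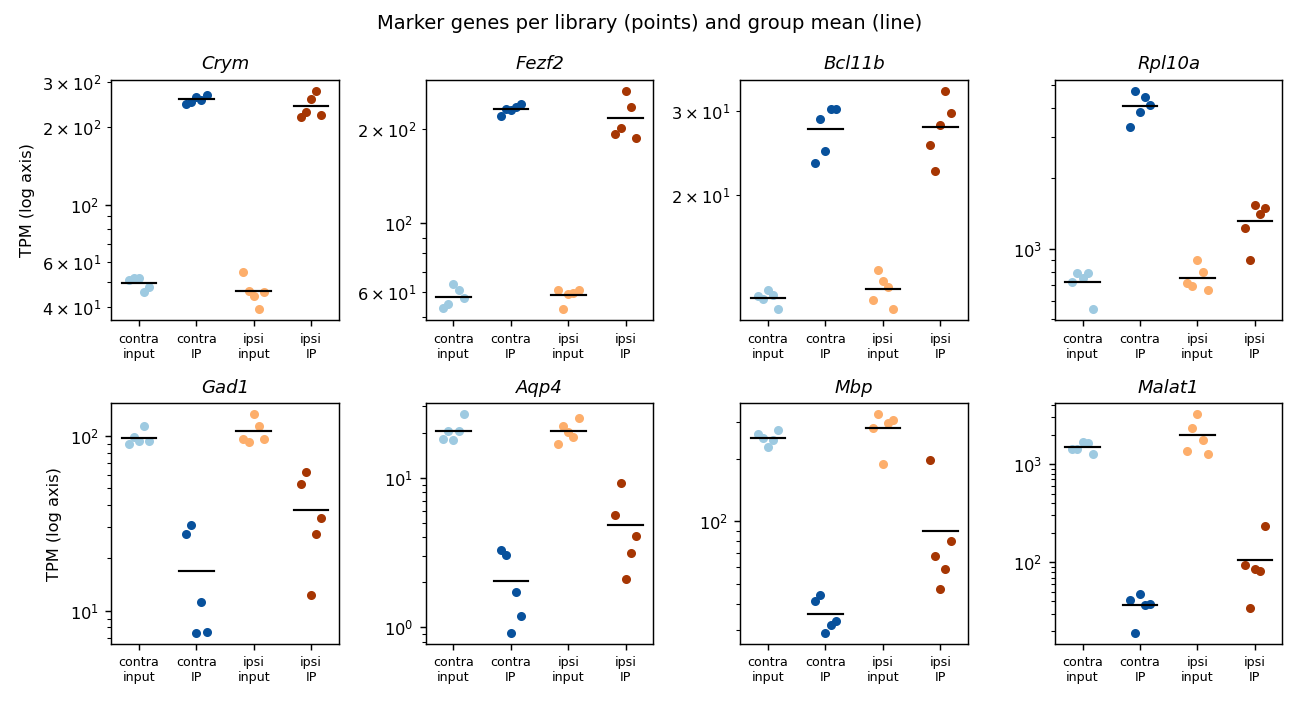
TPM of 8 genes (log axis) in each of the 20 libraries, by group. Each point is a library and each line a group mean (n = 5). Crym and Fezf2 sit higher in both IP groups than in the inputs, Gad1, Aqp4, Mbp and Malat1 sit lower, and Rpl10a is highest in contra IP, at 4083 TPM on average.

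Of 20 tested genes of the layer 5b corticospinal list, 18 were higher in contra IP and 1 lower, over all genes and adjusted over the list alone, with a median log2 of 1.32. In limma's camera the list had an adjusted p = 2.5e-21 with a preset correlation and adjusted p = 0.12 with an estimated correlation. Besides Crym and Fezf2 these included Igfbp4 (log2 2.24 ± 0.06), Pou3f1 (1.43 ± 0.08) and Bcl11b, also known as Ctip2, a transcription factor needed for corticospinal axon growth (1.10 ± 0.10). Hpgd, a prostaglandin-degrading enzyme, was the member that was lower (-2.04 ± 0.22), and Npnt, singled out after its values were seen, was not called (-0.24). Crym (gene ID 12971) lies on chromosome 7 from 120186380 to 120201989, Fezf2 (54713) on chromosome 14 from 12338992 to 12346803 and Bcl11b (58208) on chromosome 12 from 107910403 to 108004145, all protein-coding (GRCm38.p6). Genes of other cortical projection neurons went the other way. All 12 of 12 tested genes of the list for intratelencephalic neurons of layers 2 to 4 were lower (median log2 -2.08), among them Rorb (-2.25 ± 0.10) and Cux1 (-2.19). That list had an adjusted p = 0.00015, and adjusted p = 0.35 with an estimated correlation. Of 9 layer 6 genes 8 were lower (median -1.15), among them Rprm (-2.86) and Tbr1 (-1.08). That list had an adjusted p = 0.010, and adjusted p = 0.35 with an estimated correlation. The list for intratelencephalic and near-projecting neurons of layer 5 was mixed, with Lypd1 (1.58) and Etv1 (0.38) higher and Tshz2 (-2.86), Deptor (-2.06) and Slc17a8 (-0.86) lower among 7. It was not called (camera adjusted p = 0.21), with a median of 0.27, a mean of -0.46 and the test upward. Of 10 genes shared by excitatory neurons, 2 were higher and 5 lower (3 and 5 adjusted over the list alone). The list was not called (adjusted p = 0.15, median -0.09, test upward). The adjusted p was 0.35 with an estimated correlation. After scaling 5 were higher and 1 lower (adjusted p = 0.042), and Camk2a, a kinase of excitatory synapses, turned from -0.23 to 0.081. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had 175.5 ± 22.1 TPM in IP and 162.7 ± 14.5 in input (SD, n = 5 each). Limma did not call this difference (log2 0.10 ± 0.06, adjusted p = 0.15, higher in 4 of 5 pairs) until scaled (0.42, adjusted p = 0.00017).

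Every tested astrocyte gene (10 of 10, median log2 -2.31), oligodendrocyte gene (12 of 12, -2.51), oligodendrocyte precursor gene (6 of 6, -1.58) and microglia gene (12 of 12, -1.65) was lower in contra IP than in its input. So were 16 of 17 interneuron genes (median -2.43). The camera adjusted p was 0.0003, 0.00015, 0.019, 0.0027 and 0.00015 for these lists, and adjusted p = 0.39, 0.39, 0.35, 0.35 and 0.35 with an estimated correlation. The steepest interneuron falls were Npy, a neuropeptide (-4.56 ± 0.13), and Sst, the peptide somatostatin (-3.47 ± 0.19). Lamp5 was the member that was higher (0.28 ± 0.06, adjusted p = 0.0021). Myelin genes Ermn (-3.66) and Mobp (-3.18) and the microglial genes C1qb (-2.76), P2ry12 (-2.71) and Cx3cr1 (-1.06 ± 0.16) showed the same direction. Of 7 vascular and meningeal genes, 6 were lower and Itm2a was higher (0.83) (adjusted p = 0.31). Cldn5, a tight junction gene of endothelium, was under the filter on low values in every IP comparison. Both tested globin genes were lower, Hba-a2 (-2.96) and Hbb-bs (-3.63), which have near-identical copies and are uncertain. The choroid plexus list had Ttr alone, lower (-1.80). Of 6 striatal and subcortical genes, 5 were lower, among them Drd1 (-1.45), with a median of -1.61. That list had an adjusted p = 0.034, and adjusted p = 0.35 with an estimated correlation.

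All 8 nuclear noncoding RNAs of the list were lower in contra IP (median log2 -2.17), with an adjusted p = 0.00013, and adjusted p = 0.12 with an estimated correlation. Malat1, a nuclear-speckle RNA, had 1495 ± 169 TPM in contra input and 36.5 ± 10.6 TPM in contra IP (SD, n = 5 each), 41.4-fold lower (log2 -5.37 ± 0.14). Meg3 (-4.03 ± 0.09) and Snhg11 (-3.47) followed. Among the 10 largest falls picked by rule, AF357426 (-5.90), Mir186 (-5.55), Bc1 (-5.45), AF357425 (-5.12), Mir128-1 (-5.10), AF357355 (-4.98), Scarna3a (-4.80) and Mir568 (-4.75) were genes of small RNAs. Most lie inside longer genes whose reads they can share and are uncertain for that reason. Lrrc17 (-4.89) was protein-coding.

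Genes of axons went both ways in the contra IP, and most nuclear-encoded genes of oxidative phosphorylation were higher. Gap43, the growth-cone protein, had 699.1 ± 59.1 TPM (SD, n = 5), 3.17-fold its input (log2 1.67 ± 0.07, adjusted p = 3.6e-08). Of 19 axon growth and regeneration genes, however, 14 were lower and 2 higher (median -0.64, camera adjusted p = 0.50), with Sox11 (-1.83) and Klf6 (-1.05) among the lower. Neurofilament subunits Nefm (1.82 ± 0.09), Ina (1.37) and Nefl (1.26) and the tubulin Tubb3 (1.43) were the 4 of 12 neurofilament and axonal transport genes that were higher. Another 6, such as Kif5a (-0.84) and Mapt (-0.63) were lower. That list's median was -0.10, its mean 0.24 and its test upward (adjusted p = 0.022, and adjusted p = 0.45 with an estimated correlation). After scaling the adjusted p was 0.063, with 6 higher and 3 lower. Of 34 axon guidance genes 10 were higher, among them Nrp1, a semaphorin receptor (0.83 ± 0.10), Ephb1 (0.87), Slit3 (0.81) and Sema3c (0.60). Another 15 were lower, among them Sema3a (-1.94), Dcc, the netrin receptor (-1.67), Fzd3 (-1.45) and Ryk (-1.11). Its median was -0.11 and mean -0.23 with the test upward (adjusted p = 0.022, and adjusted p = 0.44 with an estimated correlation). After scaling the adjusted p was 0.089, with 16 higher and 11 lower. Of 30 voltage-gated channel genes 6 were higher, led by Scn4b (1.44 ± 0.07) and Kcnn2 (1.08). Another 17 were lower, led by Kcnc2 (-3.17) and Kcnc1 (-2.23), potassium channels of fast-spiking interneurons. The list was not called (adjusted p = 0.55, median -0.28, test upward), with 12 higher and 9 lower after scaling. Of 94 nuclear-encoded genes of oxidative phosphorylation, 71 were higher and 7 lower (73 and 7 adjusted over the list alone). The median was 0.39, with an adjusted p = 7.7e-32, and adjusted p = 0.35 with an estimated correlation. Cox7a1, a cytochrome oxidase subunit, was 5.51-fold higher (log2 2.46 ± 0.14), Uqcrc1 (0.65) and Atp5g1 (0.75) less so, while Cox6a2 was lower (-3.83). None of the mitochondrially encoded genes of the list was in the table. Ribosomal protein genes, many of which share sequence with pseudogenes, were lower for 71 of 80 (73 adjusted over the list alone), with a median of -0.44, an adjusted p = 0.00015, and adjusted p = 0.59 with an estimated correlation. After scaling 33 were lower and 3 higher (adjusted p = 0.052). Among 14 immediate early genes Egr4 (0.78) and Dusp1 (0.70) were higher and 7 lower, such as Egr3 (-1.19) and Egr1 (-0.99). The list was not called (adjusted p = 0.69, median -0.26, test upward), with 4 higher and 5 lower after scaling. All 6 interferon-response genes were lower, for example Ifih1 (-1.50) and Isg15 (-1.43) (adjusted p = 0.15).

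Of the genes named by rule, the largest rises in contra IP were of Kalrn, a guanine-nucleotide exchange factor of synapses, at 2180 ± 447 against 110.1 ± 5.18 TPM (SD, n = 5 each, log2 4.27 ± 0.10, adjusted p = 1.8e-09). Next came Ctse (3.69), Atg7, an autophagy enzyme (3.55), Wdr92 (3.48), Olfr1033 (3.33), AI506816 (3.15), Tnrc18 (2.80), Serpina3n (2.58 ± 0.14), Pdlim1 (2.51 ± 0.09) and Rpl10a. Rpl10a, a large-subunit ribosomal protein that is the tagged subunit in common TRAP constructs, had 4083 ± 546 TPM in contra IP and 722.4 ± 98.4 TPM in contra input (SD, n = 5 each, log2 2.50 ± 0.10, adjusted p = 2.7e-08). The labels used here do not name the tagged protein. In all, limma called 1327 of 12917 tested genes higher and 7219 lower in contra IP at an adjusted p under 0.05. After median-ratio scaling 3072 were higher and 4425 lower, and 1327 and 4425 were called on both scales. At least 2-fold were 149 higher and 2046 lower. The 135 genes named by rule that were called stayed called when each replicate was left out and with no block on replicate.

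**Figure D2:**
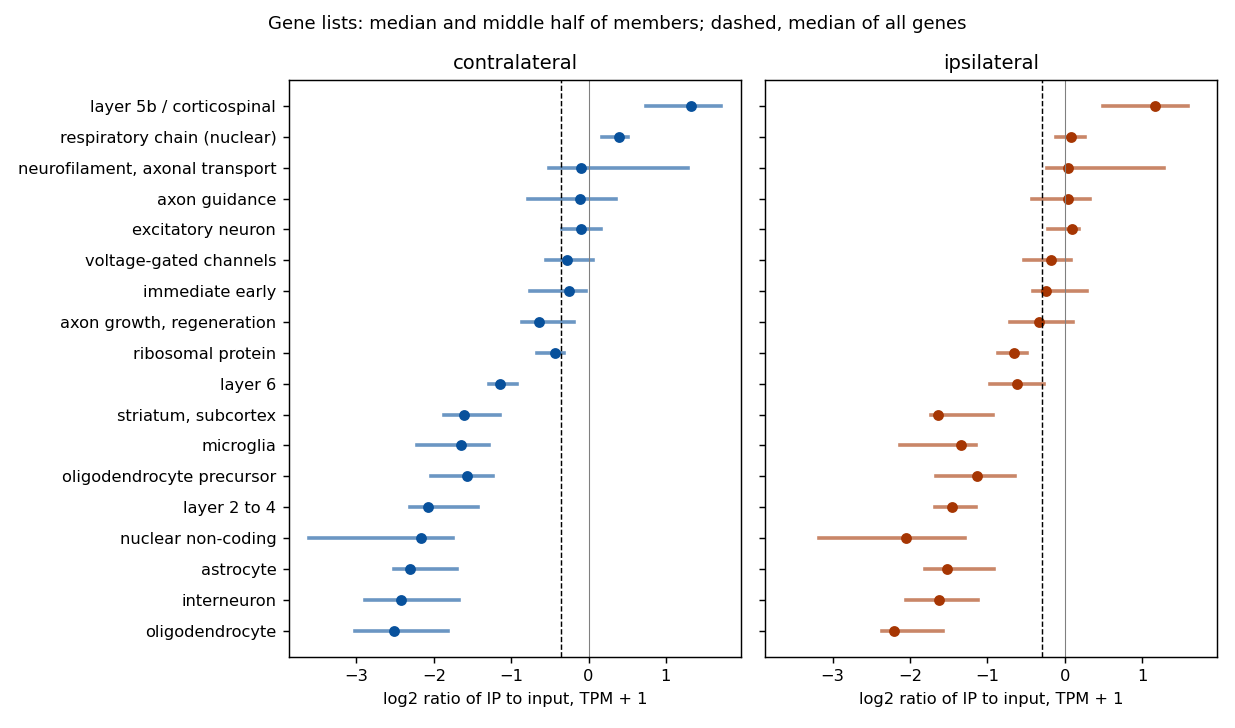
Median log2 fold change of IP over input (x axis) for 18 gene lists, per side, with bars from the 25th to the 75th percentile of the list's genes. The dashed lines mark the median of all tested genes (-0.35 contra, -0.30 ipsi). The layer 5b list lies farthest right on both sides (1.32 and 1.16), and the lists of glia, interneurons and nuclear RNA lie left of the dashed lines.

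The ipsi IP was compared with its input in the same way, for the CSNs whose axons reach the side of the cord on their own side of the brain. The same markers were higher in the IP. Crym had 240.7 ± 25.3 TPM in ipsi IP and 45.9 ± 5.58 TPM in ipsi input (SD, n = 5 each, 5.16-fold, log2 2.37 ± 0.12 SE). Fezf2 had 217.1 ± 33.3 and 58.9 ± 3.38 TPM (3.61-fold, log2 1.85 ± 0.11 SE). Igfbp4 (2.25 ± 0.11), Cdh13, a cadherin (1.45 ± 0.12), and Bcl11b (1.06 ± 0.14) were also higher, in 5 of 5 pairs each, with limma adjusted p from 4.4e-06 for Igfbp4 to 0.00053 for Bcl11b. Glial and interneuron genes were lower. Gad1 was at 37.8 ± 20 against 106.1 ± 17.3 TPM (log2 -1.64 ± 0.33 SE, adjusted p = 0.0037), Aqp4 at 4.81 ± 2.76 against 20.7 ± 3.2 TPM (-2.01 ± 0.24 SE, 0.00026) and Mbp at 90 ± 60.6 against 280.6 ± 54.2 TPM (-1.80 ± 0.23 SE, 0.00035, with SD of TPM and n = 5 each), lower in 5 of 5 pairs each.

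By list, 14 of 20 layer 5b corticospinal genes were higher in ipsi IP and 1, Hpgd (-1.49), lower (15 and 2 adjusted over the list alone). The median log2 was 1.16, with a camera adjusted p = 2.5e-19, and adjusted p = 0.075 with an estimated correlation. All 12 genes of layers 2 to 4 were lower (median -1.46, adjusted p = 7e-06), such as Lhx2 (-2.12) and Rorb (-1.86). So were 16 of 17 interneuron genes (median -1.63, adjusted p = 1.8e-05), such as Npy (-3.36 ± 0.27), Sst (-2.64) and Pvalb (-2.06). Lower too were 10 of 11 oligodendrocyte genes (median -2.21, adjusted p = 1.8e-05), such as Ermn (-2.76), and 11 of 12 microglia genes (median -1.33, adjusted p = 0.00025), such as Aif1 (-2.89) and Cx3cr1 (-1.24). Of 5 striatal genes 4 were lower (median -1.64, adjusted p = 0.022). These 5 lists each had an adjusted p = 0.30 with an estimated correlation. Astrocyte genes were lower for 10 of 11 (11 adjusted over the list alone), such as Slc1a2, a glutamate transporter (-1.52). Their median was -1.52, with an adjusted p = 0.00027, and adjusted p = 0.33 with an estimated correlation. Lamp5 was again the interneuron gene that was higher (0.40 ± 0.14, adjusted p = 0.040). Of 9 layer 6 genes 5 were lower, such as Rprm (-2.16) and Tbr1 (-0.62), and the list was not called (median -0.62, adjusted p = 0.058, and adjusted p = 0.32 with an estimated correlation) until scaled (0.044). Of 6 precursor genes 4 were lower, such as Olig1 (-2.75), and Cspg4 was higher (1.70 ± 0.38, adjusted p = 0.0068). That list was not called (adjusted p = 0.23), with 1 higher and 5 lower adjusted over the list alone. The remaining cell lists were not called. These were layer 5 intratelencephalic and near-projecting (1 higher and 2 lower of 6, adjusted p = 0.51), vascular and meningeal (0 and 4 of 7, 0.38) and excitatory neurons (2 and 2 of 10, 0.051), the last with 5 and 1 after scaling (0.016), and adjusted p = 0.32 with an estimated correlation as deposited. Both globin genes, Hbb-bs (-3.36) and Hba-a2 (-2.38), were lower, and no choroid plexus gene was tested.

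All 8 nuclear noncoding RNAs were lower (median log2 -2.05), with an adjusted p = 6.5e-05, and adjusted p = 0.30 with an estimated correlation. Malat1 was at 105.9 ± 75.6 TPM in ipsi IP and 1993 ± 801 TPM in ipsi input (SD, n = 5 each, log2 -4.39 ± 0.40). The 4 neurofilament and tubulin genes that were higher in contra IP were higher here too, Nefm (1.82 ± 0.10), Ina (1.54), Tubb3 (1.32) and Nefl (1.27). Another 2 of the 12 were lower (adjusted p = 0.00027, and adjusted p = 0.30 with an estimated correlation). Gap43 was 2.74-fold higher (1.45 ± 0.11, adjusted p = 2.3e-05). Of 19 axon growth genes 3 were higher and 9 lower (4 and 10 adjusted over the list alone, 5 and 5 after scaling), and the list was not called (adjusted p = 0.82). Of 34 axon guidance genes 6 were higher, among them Slit3 (0.98), Unc5c (0.69), Nrp1 (0.67) and Robo1 (0.67). Another 9 were lower, such as Sema3a (-1.24) and Fzd3 (-1.13). The counts were 6 and 10 adjusted over the list alone, and 12 and 4 after scaling. That list's median was 0.04, its mean -0.05 and its test upward (adjusted p = 0.0019, and adjusted p = 0.30 with an estimated correlation). Channel genes Scn4b (1.30) and Kcnn2 (0.96) were among 3 of 30 higher, and Kcnc2 (-2.17) and Kcnc1 (-1.55) among 10 lower (adjusted p = 0.51, with 6 and 4 after scaling). Of 94 oxidative phosphorylation genes 19 were higher, led by Cox7a1 (2.13 ± 0.19), and 12 lower, led by Cox6a2 (-3.05). The counts were 18 and 12 adjusted over the list alone, and 39 and 6 after scaling. The median was 0.08, the mean -0.03 and the test upward (adjusted p = 9.3e-08, and adjusted p = 0.30 with an estimated correlation). Ribosomal protein genes were lower for 73 of 80 (77 adjusted over the list alone, 46 after scaling), for example Rpl30 (-1.30) and Rpl32 (-1.22). Their median was -0.66, with an adjusted p = 1.6e-14, and adjusted p = 0.32 with an estimated correlation. Of 14 immediate early genes 3 were higher, Btg2 (1.01), Egr4 (0.88) and Dusp1 (0.50), and 3 lower (4 adjusted over the list alone, 5 and 1 after scaling, list adjusted p = 0.15). Of 6 interferon-response genes 5 were lower (adjusted p = 0.15).

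Kalrn again led the rises of the genes named by rule, at 10932 ± 8362 TPM in ipsi IP (SD, n = 5; range 2854 to 24140) against 111.4 ± 4.83 TPM in ipsi input (log2 6.24 ± 0.36, adjusted p = 7.8e-06). Next came Atg7 (5.68), Ctse (4.98), Wdr92 (4.80), Olfr1033 (4.65), AI506816 (4.47), Tnrc18 (4.23), Yeats2 (4.20), Ubr3 (3.98) and Bahcc1 (3.46). Rpl10a was 1.72-fold higher (1313 ± 260 against 754.7 ± 90.7 TPM, SD, n = 5 each, log2 0.78 ± 0.11, adjusted p = 0.00079). The largest falls included Mir186 (-6.10), Mir128-1 (-6.03), Snord4a (-5.59), AF357426 (-5.25) and Lrrc17 (-4.92). In all 742 of 12997 genes were higher and 4459 lower, and 1560 and 2470 after scaling, with 741 and 2470 called on both scales. Within replicates 1, 2 and 4, which may form a sequencing run apart from 5 and 7 since a numbering in the labels restarts there, 294 were higher and 2785 lower, and within 5 and 7, 572 and 2238. The contra comparison gave 969 and 6030, then 941 and 5361. By Ddx3y, replicates 1 and 2 were male and 4, 5 and 7 female. Sex and such a run can thus not be fully told apart, here or in the other comparisons. Without replicate 5, 481 genes were higher in all, 5 axon guidance genes lower, 6 channel genes lower and 1 axon growth gene higher. Without replicate 2, 3 axon guidance genes were higher, 6 channel genes lower, 2 interferon genes lower (2 also without replicate 4), and 11 oxidative phosphorylation genes higher and 7 lower (7 also without replicate 1). Of 130 genes named by rule that were called, 118 stayed called whichever replicate was left out, and 127 with no block.

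The enrichments of both sides ran together, with a Pearson correlation of their log2 fold changes of 0.87 across 12735 genes tested in both (genes are not independent replicates, and both sides came from the same mice). Of the genes higher in IP, 598 were shared, where independent lists of the same lengths would share 74.7. Of those lower, 4053 were shared, against 2448. After scaling the shared numbers were 1369 (370 for independent lists) and 2172 (824). Of genes called on both sides, 8 were higher in contra IP and lower in ipsi IP than in their inputs, and 7 the reverse.

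The IPs of both sides were then compared, which asks how CSNs of the hemisphere opposite the injection differ from those of the same side. Crym, Fezf2 and Bcl11b, markers of the target neurons, and Slc17a7 were not called. Crym differed by log2 0.09 ± 0.08 (SE, limma adjusted p = 0.52), Fezf2 by 0.11 ± 0.09 (0.50) and Bcl11b by -0.01 ± 0.11 (0.97). Slc17a7, at 175.5 ± 22.1 and 184.6 ± 26.7 TPM (SD, n = 5 each), differed by -0.07 ± 0.08 (0.64). Rpl10a was 3.14-fold higher in contra IP, at 4083 ± 546 against 1313 ± 260 TPM (SD, n = 5 each, log2 1.65 ± 0.14 SE, adjusted p = 0.0011). Dancr, a long noncoding RNA that hosts small nucleolar RNAs, was at 22.3 ± 3.41 against 4.98 ± 1.63 TPM (1.99 ± 0.18, 0.0011) and Snhg3, a host gene of the same kind, was 2.66-fold higher (1.41 ± 0.12, 0.0011). These 3 genes moved the same way in 5 of 5 pairs and stayed called whichever replicate was left out, which held for 4 of 50 called genes named by rule in this comparison. With no block on replicate, 6 of the 50 stayed called. Rpl10a, Dancr and Snhg3 were among them. Over all alternatives limma's adjusted p ran from 3.8e-06 to 0.11 for Rpl10a, 9.7e-06 to 0.070 for Dancr and 0.00017 to 0.070 for Snhg3. Rpl10a (gene ID 19896) lies on chromosome 17 from 28328471 to 28331033, Dancr (70036) on chromosome 5 from 74093060 to 74094337 and Snhg3 (399101) on chromosome 4 from 132351933 to 132353686 (GRCm38.p6).

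As lists, genes of oligodendrocytes, astrocytes, interneurons and layers 2 to 4 and 6 leaned to ipsi IP with a preset correlation. In all of these but the first most members were not called. Oligodendrocyte genes were lower for 6 of 11, including Cnp (-1.20) and Mbp (-1.13 ± 0.20), and for 7 adjusted over the list alone (median log2 -0.98, camera adjusted p = 5.4e-06). Astrocyte genes were lower for 4 of 10, such as Slc1a2 (-0.95), Gja1, a gap junction protein (-1.09), and Aqp4 (-0.89). The count was 8 adjusted over the list alone and 1 after scaling (median -0.91, adjusted p = 2.4e-06). Interneuron genes were lower for 5 of 14, such as Npy (-1.28 ± 0.20), Gad1 (-1.17 ± 0.18), Gad2 (-1.04) and Sst (-0.86 ± 0.11). Pvalb, a calcium-binding protein of fast-spiking interneurons, was higher (0.65 ± 0.12, adjusted p = 0.027). Adjusted over the list alone 1 was higher and 7 lower (median -0.70, adjusted p = 0.00015, 0.012 with no block). Layer 6 genes were lower for 3 of 7, Ctgf (-0.84), Tbr1 (-0.55) and Tle4 (-0.53), and for 6 adjusted over the list alone (median -0.55, adjusted p = 0.00093). These 4 lists had an adjusted p = 0.21 with an estimated correlation. Genes of layers 2 to 4 were lower for 2 of 12, Cux2 (-1.07) and Rasgrf2 (-1.01), and for 7 adjusted over the list alone. Their median was -0.49, with an adjusted p = 0.0006, and adjusted p = 0.26 with an estimated correlation. Nuclear noncoding RNAs were lower for 1 of 6, Malat1 (-1.31 ± 0.22), and for 5 adjusted over the list alone. Their median was -0.62, with an adjusted p = 0.0061, and adjusted p = 0.39 with an estimated correlation. Precursor genes gave 0 of 4 (2 lower adjusted over the list alone, list adjusted p = 0.036, 0.095 with no block, and adjusted p = 0.26 with an estimated correlation). The layer 5b list leaned to contra IP (median 0.09), with an adjusted p = 0.00039, and adjusted p = 0.26 with an estimated correlation. Its median was above 0 in 3 of 5 pairs. In replicate 4 it was -0.131, or 0.026 above that of all genes. Of its 19 genes 1 was called, Pcp4, a calmodulin-binding peptide, at 7261 ± 698 against 4040 ± 894 TPM (SD, n = 5 each, log2 0.87 ± 0.13, adjusted p = 0.018).

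Genes of oxidative phosphorylation leaned to contra IP, with 4 of 92 called, Cox7b2 (1.54, listed at 0 in some ipsi IP libraries), Uqcrb (0.51 ± 0.08), Ndufab1 (0.47 ± 0.07) and Atp5j2 (0.44). The count was 19 adjusted over the list alone and 23 after scaling. The median log2 was 0.23, with an adjusted p = 1.5e-30, and adjusted p = 0.21 with an estimated correlation. It was above 0 in 4 of 5 pairs. In replicate 4 it was -0.148, or 0.0089 above that of all genes. A linear fit of the side difference on transcript length brought the list's median, taken from that of all genes, from 0.349 to 0.163. Ribosomal protein genes leaned the same way, with 2 of 81 called, Rps27l (0.56) and Rps28 (0.45), and 18 after scaling. Their median was 0.14, with an adjusted p = 1.6e-18, and adjusted p = 0.28 with an estimated correlation. It was above 0 in 4 of 5 pairs. In replicate 4 it was -0.126, or 0.030 above that of all genes. In the same fit on length it went from 0.26 to 0.0957 above that of all genes. Axon guidance genes leaned to ipsi IP, with Sema3a (-0.90) and Epha4 (-0.52) of 33 lower and 0 after scaling. Their median was -0.26, with an adjusted p = 0.036, 0.063 with no block, and adjusted p = 0.21 with an estimated correlation. The neurofilament and transport list did so too, with Spock1 (-0.47) and Kif5c (-0.40) of 12 lower (4 adjusted over the list alone, 0 after scaling). Its median was -0.23 (adjusted p = 0.037, 0.095 with no block, 0.20 after scaling, and adjusted p = 0.43 with an estimated correlation). Channels (1 of 30 lower, Kcnc2 at -1.16, adjusted p = 0.22), immediate early genes (0 of 14, 5 lower adjusted over the list alone, 0.37) and excitatory neurons (0 of 10, 1 higher and 2 lower adjusted over the list alone, 0.36) were not called as lists. Nor were axon growth (0 of 16, adjusted p = 0.14), layer 5 intratelencephalic and near-projecting (0 of 6, 0.55), microglia (0 of 5, 0.31) and striatum (0 of 4, 0.10). The vascular, blood and interferon lists had under 4 tested genes.

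Of the genes named by rule, the largest rises toward contra IP were Mir1900, a microRNA gene (3.50 ± 0.47, adjusted p = 0.011), Rab26os, an antisense transcript (2.20 ± 0.40), Dancr, Rpl10a, Snhg3, Snhg20 (1.37 ± 0.23), Snhg4 (1.22 ± 0.19), Sv2c, a synaptic vesicle protein (0.89 ± 0.15), Vsig2 (0.89 ± 0.15) and Snhg10 (0.87 ± 0.12). Whether counting used the strand is not given in the sources used here, so Rab26os is uncertain, as is Mir1900, which lies at 21032251 to 21032328 on chromosome 9 within the span of Icam5. The Snhg genes overlap the small nucleolar RNA genes that they host. The largest falls included Mir568 (-2.64), Atg7 (-2.20 ± 0.35), Kalrn (-1.98 ± 0.33), Ubr3 (-1.83), Yeats2 (-1.78), Strip2 (-1.66), Exph5 (-1.65), Shank2, a postsynaptic scaffold (-1.61 ± 0.19, adjusted p = 0.0082), and Hic2 (-1.57). In all 37 of 12011 genes were higher in contra IP and 265 lower, and 214 and 191 after scaling (12.3% and 52.8% of calls higher), with 37 and 188 on both scales. These counts rested on few pairs. Without replicate 2, 3 higher and 7 lower were called, with 4 and 6 without 5, 8 and 29 without 7, 22 and 199 without 1, and 159 and 262 without 4. They were 7 and 6 with no block on replicate, 3 and 2 in replicates 1, 2 and 4, and 31 and 309 in 5 and 7. The list members called moved likewise. With no block they were 0 in all 7 lists of glia, interneurons, other layers, oxidative phosphorylation and ribosomal proteins. Oligodendrocyte genes lower fell to 1 without replicate 2 or 5 and 2 without 7, interneuron genes lower to 1, 0 and 2 without 2, 5 and 7, and astrocyte and layer 2 to 6 genes lower to 0 without 2, 5 or 7. Oxidative phosphorylation genes higher were 0 without 2, 5 or 7 and 38 without 4, and ribosomal protein genes higher 18 without 4 and 0 without any other.

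**Figure D3:**
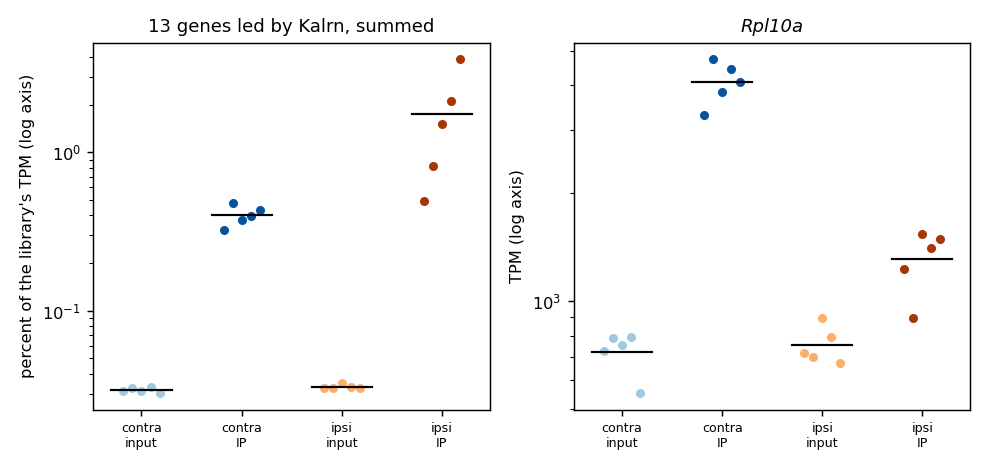
Summed share of TPM of 13 genes over 8-fold higher in ipsi IP than ipsi input, in percent, and TPM of Rpl10a, per library (log axes), with lines at group means (n = 5). The 13 genes run from 0.49 to 3.86% in ipsi IP and from 0.321 to 0.479% in contra IP, while Rpl10a is higher in contra IP in each replicate.

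The inputs of both sides were compared as the background for these differences. No gene was called among 13380 by limma, as deposited or after scaling, where 627 and 537 genes had an unadjusted p under 0.05. Rpl10a was at 722.4 ± 98.4 TPM in contra and 754.7 ± 90.7 TPM in ipsi input, and Dancr at 10.5 ± 2.48 and 9.31 ± 1.91 TPM (SD, n = 5 each). The smallest p belonged to Mir3064 (log2 -0.60 ± 0.06, adjusted p = 0.092, lower in 5 of 5 pairs), followed by Mir6390 (1.18 ± 0.15, adjusted p = 0.20) and Rsc1a1 (-1.01, adjusted p = 0.41). As a list, the 12 oligodendrocyte genes were lower in contra input (median -0.28), with a camera adjusted p = 1.3e-05, and adjusted p = 0.62 with an estimated correlation. Of them 0 were called over all genes and 5 adjusted over the list alone. The 14 immediate early genes were higher as a list (median 0.06, adjusted p = 0.027, 0.10 with no block, and adjusted p = 0.62 with an estimated correlation) with 0 called. No other list was called as deposited, and after scaling the striatal and subcortical list was too (median -0.24 as deposited, adjusted p = 0.072, 0.045 after scaling, and adjusted p = 0.62 with an estimated correlation). Leaving out any replicate left 0 called genes.

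Last, the enrichment of IP over input was compared between the sides in one fit of all 20 libraries, which takes the inputs into account. It called 4 genes with larger enrichment in contra. They were Rpl10a (log2 1.72 ± 0.19, adjusted p = 0.00074), Dancr (1.84 ± 0.25, 0.0053), Cox7b2, a cytochrome oxidase subunit (1.90 ± 0.29, 0.013), and AA467197 (2.34 ± 0.38, 0.016), the last 2 of which were listed at 0 in some ipsi IP libraries. It called 4 with larger enrichment in ipsi. They were Ptbp1, a splicing repressor (-1.70 ± 0.23, 0.0048), Ipw, an imprinted noncoding RNA (-1.54 ± 0.25, 0.016), and the neuronal calcium sensors Hpca (-0.79 ± 0.14, 0.040; 0.061 after scaling) and Hpcal4 (-0.60 ± 0.09, 0.016). Each had the same direction in 5 of 5 replicates. Ptbp1 was at 2.89 ± 0.344 TPM in contra IP and 10.7 ± 2.66 TPM in ipsi IP, against 7.6 ± 1.13 and 6.83 ± 1.05 TPM in the inputs, and Hpca at 304.5 ± 55.8 and 504.3 ± 69.3 TPM, against 1494 ± 67.6 and 1440 ± 72.8 TPM (SD, n = 5 each). Crym (-0.02 ± 0.12, adjusted p = 0.96), Aqp4 (-0.89, 0.25) and Gad1 (-1.06, 0.34) were not called. By list, the enrichment difference was negative for astrocyte (median -0.73, camera adjusted p = 4.9e-05), interneuron (-0.63, 0.00017), oligodendrocyte (-0.61, 0.0085), layer 2 to 4 (-0.39, 0.0019) and layer 6 genes (-0.46, 0.0070). Adjusted over the list alone, 5 of 11, 8 of 18, 6 of 12, 2 of 13 and 3 of 9 of these were lower, and 1 interneuron gene higher. The difference was positive for oxidative phosphorylation (0.28, 3.5e-27), ribosomal protein (0.21, 5.4e-15) and layer 5b genes (0.09, 0.0070), with 3 of 95, 0 of 81 and 1 of 20 higher adjusted over the list alone. With an estimated correlation the adjusted p = 0.40 for oligodendrocyte and ribosomal protein genes and adjusted p = 0.31 for the other 6 lists. No other list was called as deposited, and after scaling the precursor list was too (median -0.38 as deposited, adjusted p = 0.056, 0.023 after scaling, and adjusted p = 0.31 with an estimated correlation). Of the 8 genes Rpl10a alone stayed called whichever replicate was left out (highest adjusted p = 0.047), and 4 stayed called with no block. With a block for each side of each replicate 6 stayed called, and Hpca (adjusted p = 0.090) and Hpcal4 (0.070) did not. The fit on replicates 1, 2 and 4 called 0 genes and that on 5 and 7 called 7 and 65. Over all 13689 genes 1823 had an unadjusted p under 0.05, and after scaling 9 were higher and 6 lower.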

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

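The test against the level in corticospinal neurons of both sides and the permutation test of equal carried-over shares were chosen only after the result was seen, the latter in place of a ratio of a pair of lists that had been picked from the shares themselves.

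The first pattern is a set of 13 genes over 8-fold higher in ipsi IP than in its input, Kalrn, Atg7 and Ctse among them (Gm12505, Lrguk and Rsph3b, also in it, were singled out after their values were seen). Together they took 1.75% ± 1.33 of the TPM in ipsi IP (0.49, 0.823, 1.51, 2.1 and 3.86% in replicates 1, 2, 4, 5 and 7), 0.401% ± 0.06 in contra IP, and 0.0331% and 0.0316% in the ipsi and contra inputs (SD, n = 5 each). The tables argue against sequence shared between these transcripts (0% of gene pairs had a 31-base word in common, against a median of 1.28% and a 95th percentile of 8.97% in random sets). Only annotated transcripts were compared with each other, so sequence outside them and shorter matches are not covered. For genes picked on the ipsi side, the tables also argue against an equal level in the target neurons of both sides. For that test genes were picked by the same bounds without a replicate, 11 without replicate 7 and 13 without any other, and read in that replicate alone, since the 13 genes had been chosen for high values in ipsi IP. Their median contra minus ipsi IP log2 difference was -0.4, -0.78, -1.26, -2.12 and -2.93 in replicates 1, 2, 4, 5 and 7 (median -1.26), against 0.171, 0.204, -0.131, -0.012 and 0.262 for layer 5b genes. The 13 genes were also called higher in contra IP than in contra input (log2 from 1.37 for Lrguk to 4.79 for Gm12505). Enrichment in the target neurons of both sides, at unequal levels, is therefore not argued against by these calls. Within ipsi IP, however, the share ran from 0.49 to 3.86%, while Crym ran from 219 to 277 TPM and Fezf2 from 188 to 266 TPM. This argues against 1 fixed level in the ipsi target neurons as the whole source. Levels that differed between replicates, of which 1 and 2 were male, are not argued against. The 13 genes moved together over the 10 IP libraries once centred within side (median pairwise correlation 0.879, against a median of 0.147 and a 95th percentile of 0.388 in 1000 random sets matched on level). A single source of reads in the IP, such as the pulldown or library step, is a candidate explanation. The correlation cannot decide on it, since the genes were picked from these libraries and the random sets were not matched on spread. A shared change in the labelled cells would give such a correlation too. A difference between ipsilateral and contralateral CSNs stays open and untested, since the IP of cortex without virus was not analysed here.

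The second pattern is the lean to ipsi IP of the oligodendrocyte, precursor, astrocyte, interneuron, nuclear RNA and layer 2 to 4 and 6 lists, which were called with a preset correlation alone. A uniform share of cortex RNA carried into ipsi IP is argued against as the sole source of the lean. The input RNA needed to make the IPs equal differed over 7 lists. Its median ran from 5.34% for nuclear RNA and 6.51% for interneurons to 25.8% for layer 6 and 32.6% for astrocytes. A permutation test of the Friedman statistic gave p = 0.00038, and 0.00042 after scaling (n = 5). Any inequality counts in that test, and each share rests on a sum of TPM that highly expressed members lead. A uniform share beside other differences of such members is therefore not excluded. Transcript length as the whole cause is argued against too, as the median of 44 glial and interneuron genes stayed at -0.711 from the median of all genes after a fit on length, against -0.714 before it, although across genes the side difference fell with length (Spearman -0.391) and the oxidative phosphorylation and ribosomal protein medians dropped from 0.349 to 0.163 and from 0.26 to 0.0957 in the same fit. Carry-over of cortex RNA with unequal shares cannot be told apart from the rest, because the 5 glial, interneuron and nuclear lists had medians that differed by a ratio of 6.1 while their replicates overlapped, with microglia above 0 in 4 of 5 replicates and Pvalb going the other way (log2 0.65). A share of 10.4%, taken from these lists, predicted the direction of 270 of the 302 genes called between the IPs. Since 265 of the 302 were lower in contra IP, a guess of lower for every gene would be right for 265. The share predicted a median of -0.537 for the 44 glial and interneuron genes, against -0.83 observed. Prediction and difference share the contra IP values, so this does not decide on carry-over. Differences between the labelled cells of each side stay open and untested.

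The third pattern is Rpl10a, 1.65 ± 0.142 (log2, SE, n = 5) higher in contra IP. The other 81 ribosomal protein genes had a median of 0.145, with Rps27l (0.56) and Rps28 (0.45) called higher, which argues against an equal shift of them all as the whole difference. Reads from a virus-borne tagged Rpl10a may account for it, as that predicted a difference of over 2-fold in Rpl10a with the median of the others within 0.5, but the tag is not named in the sources used here. In the inputs Rpl10a was at 722.4 ± 98.4 TPM in contra and 754.7 ± 90.7 TPM in ipsi (SD, n = 5 each), and limma did not call it. A larger number of labelled neurons in the contralateral cortex is possible, since most corticospinal axons cross. TPM are scaled to a fixed sum, so such a number would show only as a larger share of target RNA in contra IP. The 19 tested layer 5b genes had a median of 0.09 (25th to 75th percentile 0.0071 to 0.16), with 1 called. This argues against a larger share of target RNA as the whole difference, but it does not measure the number of labelled neurons. The lean of glial and interneuron lists to ipsi IP leaves such a share open as a part of it. That number, and a difference between CSNs of each side, stay open and untested.

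The difference of IP enrichment between the sides was called by limma for 8 genes, at log2 1.72 for Rpl10a, 1.84 for Dancr, 1.9 for Cox7b2, 2.34 for AA467197, -1.7 for Ptbp1, -1.54 for Ipw, -0.787 for Hpca and -0.597 for Hpcal4. It was called with a preset correlation for 8 lists, with medians of 0.0936 for layer 5b, -0.392 for layers 2 to 4, -0.456 for layer 6, -0.629 for interneurons, -0.734 for astrocytes, -0.606 for oligodendrocytes, 0.206 for ribosomal proteins and 0.284 for oxidative phosphorylation. With an estimated correlation these lists were not called (adjusted p from 0.305 to 0.403).

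Single libraries stood far from the rest of their group in 8 of 136 groups of 5 examined, where chance marks about 1 in 20, or 6.8. In ipsi IP, replicate 4 had a layer 5b list median of log2(TPM + 1) of 5.35 (nearest 5.1) and replicate 1 an Mbp TPM of 196 (nearest 79.9). In ipsi input, replicate 4 had an interneuron list median of 4.01 (nearest 3.7) and replicate 2 a Fezf2 TPM of 53 (nearest 59.3). In contra input, replicate 7 had an astrocyte list median of 4.81 (nearest 4.32) and an Rpl10a TPM of 553 (nearest 725). In contra IP, replicate 7 had an axon guidance list median of 3.82 (nearest 3.66) and replicate 2 had 11964 genes at a TPM of at least 1 (nearest 11789).

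Other splits of the same 10 libraries, or in the difference of enrichment of the 10 pairs of IP and input, were fitted in the same way. The replicates pair the libraries, so only the 16 splits that part all 5 pairs, the real one included, can stand in for it, and these are too few for a share under 0.05. Among them the highest other gave 1 call against the real 8546 for contra IP against input, 0 against 5201 for ipsi IP against input, 1 against 302 for contra IP against ipsi IP, 1 against 0 between the inputs and 1 against 8 for the difference of enrichment. Of 100 splits drawn per comparison, the real one included, the others mostly put both members of some pairs on the same side, so they hold less contrast and decide nothing on chance. In these 100 the real count was reached by 1 split, the real one, for contra IP against input (highest other 1), ipsi IP against input (highest other 1) and contra IP against ipsi IP (highest other 50, from a split that parts replicates 4, 5 and 7 the real way). For the difference of enrichment 3 splits reached it. The highest other, at 62, parts replicates 2, 5 and 7 the real way, and the third, at 9, parts 1, 5 and 7 the real way, so both hold the contrast of sides on fewer pairs. Between the inputs, where the real count was 0, all 100 reach it by construction. Splits there that part only the input pair of replicate 4 gave the highest counts. In the blocked fit such splits rest on 1 library against 1, so these counts decide nothing about the samples.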

How the results depend on the processing

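Median-ratio scaling, alone or with no replicate block, and sample quality weights were chosen only after the data were seen. Over all alternatives and named genes, 4726 results kept their direction and side of the threshold, 515 lost the call, 11 gained it and 2 reversed; for lists 251 kept, 56 lost, 5 gained and 0 reversed. The 2 reversals were Camk2a in contra IP over input, 0.081 after scaling with and without the replicate block, which follows from the shift of the median gene. Of the list calls lost, 48 went with an estimated correlation and 4 with no replicate block. The contra IP to input counts (1327 higher, 7219 lower) moved to 3072 and 4425 with scaling and to 3026 and 4382 with scaling and no replicate block, and by under 1.5 times otherwise. Of its 8546 calls 565 changed sign after scaling, and 8 in replicates 5 and 7 alone, against 1 and 6 of the 5201 ipsi calls. The ipsi IP to input counts (742, 4459) moved to 1560 and 2470 with scaling, 1526 and 2420 with scaling and no replicate block, 294 and 2785 in replicates 1, 2 and 4, and 2238 lower in replicates 5 and 7; leaving out each replicate gave 481 to 693 higher and 3164 to 4161 lower. The counts between the IPs (37, 265) moved widely. They were 7 and 6 with no replicate block (13 of the 302 calls shared), 0 and 1 with no filter on low values (3128 at an unadjusted p under 0.05), 3 and 2 in replicates 1, 2 and 4, 159 and 1441 in the fit on all 20 libraries, 67 lower among IP-enriched genes alone, 214 higher with scaling, 17 and 7 with scaling and no replicate block, and 95 and 669 with quality weights. Leaving out each replicate gave 3 to 159 higher and 6 to 262 lower, fewest without replicate 2 or 5 (10 calls shared each) and 37 shared without 7. Between the inputs 1 gene was lower in replicates 5 and 7 and with quality weights, where as deposited limma called 0 (627 at an unadjusted p under 0.05). The difference of enrichment (4 and 4) gave 2 lower with no replicate block, 7 lower with a pseudocount of 0.1, 2 and 2 with no filter, 0 and 0 in replicates 1, 2 and 4 (695 at an unadjusted p under 0.05), 7 and 65 in replicates 5 and 7, 9 higher with scaling, 2 lower with scaling and no replicate block, 18 and 127 with quality weights, and, leaving out each replicate, 1 to 6 higher and 0 to 6 lower (0 lower without 5 or 7, with 1202 and 1121 genes at an unadjusted p under 0.05). Fewer libraries in the fit, or more genes to adjust over, can lower these counts by construction; otherwise the cause was not tested. With no replicate block, 135 of 135 named called genes kept the call in the contra, 127 of 130 in the ipsi, 6 of 50 in the between-IP comparison and 4 of 8 in the difference. It also ended 4 list calls, of the precursor, axon guidance and neurofilament lists between the IPs and of the immediate early list between the inputs. With a block for each side of each replicate the difference gave 5 higher and 4 lower, with 6 of the 8 calls shared. Count-based normalizations and tests that had been planned for a table of counts were not run, as TPM were held. Depth cannot be weighed, since TPM do not keep it.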

Other observations

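The tests by gene type and the grouping of the Snhg genes below were chosen only after the results were seen.

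Of small nucleolar, micro- and long noncoding RNA genes and of transcribed pseudogenes, the 4 classes tested, a larger share than of other genes was called lower in the IPs on both sides. After scaling, 25 of 30 tested small nucleolar RNA genes were lower in contra IP than in input (83.3%, against 34.1% of other genes; Fisher's exact test over 24 class tests, adjusted p = 2.1e-07) and 15 of 31 in ipsi IP (48.4% against 18.9%, adjusted p = 0.00068), with 0 higher on either side. Long noncoding RNA genes were lower for 293 of 553 in contra IP (53% against 33.4%, adjusted p = 3.4e-19) and 217 of 550 in ipsi IP (39.5% against 18.1%, adjusted p = 1.1e-28). MicroRNA genes were lower for 24 of 45 (53.3%, adjusted p = 0.019) and 16 of 42 (38.1%, adjusted p = 0.0084). Transcribed pseudogenes were lower for 42 of 83 (50.6% against 34.2%, adjusted p = 0.0052) and 29 of 82 (35.4% against 18.9%, adjusted p = 0.0015). Higher were 51 and 18 of the long noncoding RNA genes, in contra and ipsi IP, 5 and 2 of the transcribed pseudogenes, and 2 of the microRNA genes in each. Between the IPs, 15 of 418 long noncoding RNA genes were higher in contra IP (3.59% against 1.72%, Fisher's exact test, adjusted p = 0.019) and 5 lower (1.2% against 1.6%, adjusted p = 0.83). The other class tests between the IPs were not called. Nearby genes share transcripts and are not independent.

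Host genes of small nucleolar RNA, which carry these RNAs in their introns, were grouped after some of them were seen among the largest rises between the IPs. Of 16 tested (genes named Snhg, with Dancr and Gas5), 5 were higher in contra IP (Dancr 1.99 ± 0.18, Snhg3 1.41 ± 0.12, Snhg20 1.37 ± 0.23, Snhg4 1.22 ± 0.19 and Snhg10 0.87 ± 0.12, log2 ± SE, limma, each in 5 of 5 pairs). Dancr and Snhg3 stayed called whichever replicate was left out. The others lost the call without replicate 2 or 5 (adjusted p from 0.053 to 0.096), and Snhg20 without 7 too (0.082). Gas5 (0.19 ± 0.22) and Snhg1 (0.06 ± 0.20) were not called, and Snhg14 (-0.57 ± 0.23) and Snhg11 (-0.54 ± 0.19) had negative values. Against their inputs 5 were higher and 13 lower of 18 in contra IP, and 0 higher and 13 lower in ipsi IP; the difference of enrichment was called for 1 of 18, Dancr. No technical or biological explanation was tested for this group, and no test of the group as a whole is given, since it was picked from the same calls.

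Of the 37 genes higher in contra IP than ipsi IP, 27 were also higher and 1 lower in contra IP than in contra input after scaling, while in ipsi IP 8 were higher and 9 lower than in ipsi input. Of the 265 lower, 192 were lower and 28 higher in contra IP than in its input, and 101 were lower and 58 higher in ipsi IP than in its input. These comparisons share the IP libraries, so genes called between the IPs lean in these directions by chance too.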
